A study of Homo sapiens with 6 samples.

How the data were processed

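Messenger RNA levels were measured in human lens epithelial cells, the single layer of cells under the front capsule of the lens, and in lens cortical fiber cells, the elongated cells of the outer lens mass that arise from the epithelium. The labels give 6 samples of total RNA, each on its own Affymetrix array, 3 per cell type and numbered 1 to 3 within each type. The labels state neither how many donors or lenses were used nor whether the numbered samples came from separate tissue, so the p-values measure the spread between these arrays only, which may be technical. The number of arrays limits the precision of every value.

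The deposited table holds 1 intensity per probe set and array on a linear scale. A probe set is a group of short probes for 1 transcript. The labels call the data raw, but the mean without the lowest and highest 2% of probe sets lay between 250.15 and 250.18 on all 6 arrays, so the deposited values had been scaled per array. The software, its detection calls and its background step are not given in the sources used here. Scaling of this kind makes the arrays' averages equal and cannot show a change in total messenger RNA per cell. It also leaves in place any shift that differs between dim and bright probe sets.

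Of 22275 probe sets, 68 were Affymetrix controls. A platform annotation gave 19066 probe sets exactly 1 gene symbol, 1043 several symbols and 2166 none. The gene numbers of 19054 of the 1-symbol probe sets were found in a RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols. No genome build belongs to the intensity table, so no coordinates are given. The control probe sets, XIST and Y-linked genes were left out of the tests. Each of the 11929 genes was represented by its probe set with the highest mean over the 6 arrays, and the 7157 genes at or above the 40th percentile of that mean were tested.

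Values were used as deposited, 32 was added and log2 was taken. All fold changes are on this scale, which understates the change of dim genes. The comparison was fiber minus epithelial in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 are called higher or lower. On data simulated from the real genes' means and spread, with 200 of 7157 genes changed in each of 5 simulations, the procedure recovered 21.2% of 2-fold and 94.2% of 4-fold changes, and 5.6% of its calls were false. The simulation drew noise independently per gene and array, with no shift shared by the genes of an array. It also changed fewer genes than were called in the real data, so these rates may not hold there.

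With no detection calls at hand, a background level was set per array as the 95th percentile of 103 probe sets of 72 genes of tissues unrelated to the lens. The genes were chosen before the data were examined. The level was 138, 124 and 208 on epithelial arrays 1 to 3 and 245, 173 and 180 on fiber arrays 1 to 3. CPB1, a member of this gene set, turned out to be bright on the fiber arrays. A gene at or under the level on all 3 arrays of a group has only a bound there, given as "at least N-fold", computed from the brighter group's mean log2 value without the offset and, per dim array, the higher of the level and the gene's own value.

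Before the data were examined, 40 gene lists were fixed from textbook knowledge, 30 of lens biology and 10 of markers of other cell types. Lists with at least 5 tested members were compared with the other genes by camera in limma, with a preset correlation of 0.01 and adjustment over the 35 lists tested. Camera was also run with a correlation estimated from the residuals, which ended the call of all 15 lists (9 higher, 6 lower) past the preset test, with 0.146 as the smallest adjusted p. At an unadjusted p under 0.05, that version called 5 lists higher and 4 lower. For autophagy and for transporters of glucose, amino acids and ascorbate, the estimate was -0.007 and -0.022, under the preset 0.01. Correlation among genes therefore did not end those calls. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom of the fit. The fry test, which asks whether a list's genes move one way on balance and compares them with no other genes, had an adjusted p under 0.05 for those 15 lists and for 24 in all. Beside counts over all genes tested, the text gives counts adjusted over the list alone where they differ.

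The genes named were set by a rule fixed at the same time: the 10 largest positive and 10 largest negative log2 fold changes among called genes whose groups did not overlap and whose brighter group was above background on 3 arrays, every tested member of the lists for crystallins, fiber cell structure and lens epithelium, and up to 2 called members per direction of each other list. The rule gave 148 genes, and the text does not describe each of them. Genes named outside this rule are said to have been chosen after their values were seen.

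The numbers 1 to 3 are shared by the cell types. Deviations from the group means correlated across probe sets between same-numbered arrays at 0.303, 0.248 and 0.26, and between differently numbered arrays at -0.315 to -0.018. The deviations cancel out within a group, so the negative values follow on balance from the positive ones. Few matchings of 3 with 3 arrays exist, and the same-number one could rank highest by chance. The numbers may therefore pair the arrays, but the check cannot establish it. Pairing rests on this check alone, since the labels do not say what a number stands for, and the main fit does not use it. The fit with the number as a block was an alternative.

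The RNA quality of each array was read from the 3' and 5' control probe sets of GAPDH and ACTB, with an exact permutation test on log2 ratios. The alternatives were quantile normalization, scaling to the median, scaling on the 9 hybridization controls, offsets of 1 and 100, no filter and a 60th percentile filter, 1 common prior variance, the mean of all probe sets of a gene, all probe sets, a 2-fold threshold, the number as a block, and each array left out. After the data were examined, 3 alternatives were added: the ACTB or the GAPDH 3' to 5' ratio as a covariate, and the omission of epithelial array 3 and fiber array 1 together. Also added then were 5 further gene lists and a comparison of each called list with 10000 random lists matched on mean intensity in 40 bins. A reading of RNA quality from epithelial array 3 alone was tried first and dropped as a test, because 1 array cannot decide the question. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.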

Results

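Expression in lens epithelial cells was compared with expression in lens cortical fiber cells on 6 arrays, 3 per cell type. The comparison asks which transcripts distinguish the epithelial layer from the fiber cells that arise from it. Between 34.1% and 44.1% of probe sets were above the background level on the epithelial arrays, and between 26.9% and 32.9% on the fiber arrays. Over all probe sets but the Affymetrix controls, dim ones included, arrays of one cell type correlated at 0.864 to 0.933 (epithelial) and 0.9 to 0.95 (fiber). Arrays of different cell types correlated at 0.806 to 0.885. These correlations are across probe sets, which are not independent replicates.

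RNA quality differed along with cell type. The 3' over 5' intensity of GAPDH, which rises as RNA is degraded or incompletely copied, was 0.839, 0.75 and 3.22 on epithelial arrays 1 to 3 and 5.66, 6.34 and 6.79 on fiber arrays 1 to 3, a 4.93-fold higher ratio in fiber cells. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. For ACTB the ratios were 3.19, 1.69 and 15.7 on the epithelial and 23.1, 9.69 and 16 on the fiber arrays, 3.48-fold higher (exact permutation p = 0.2). This difference runs alongside every gene group described here, since it separates nearly the same arrays.

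**Figure D1:**
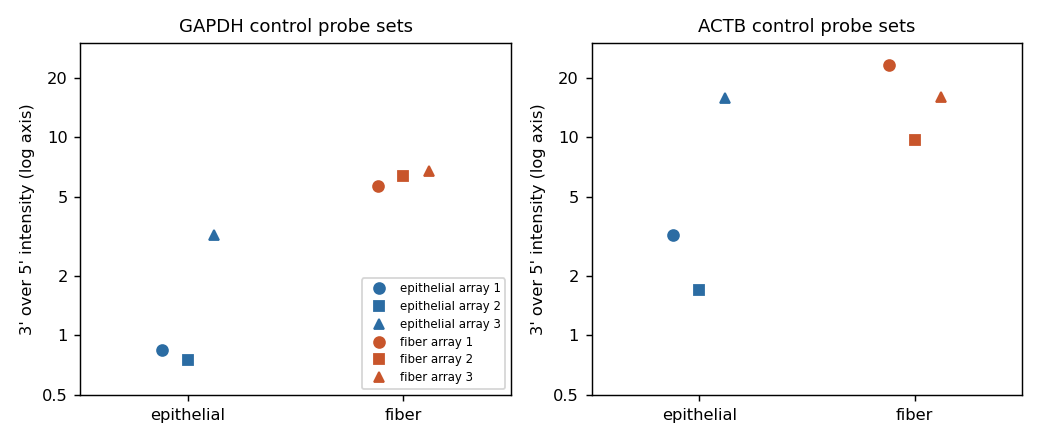
The 3' over 5' intensity ratio of the GAPDH and ACTB control probe sets (log axis, no unit) is shown for each of the 3 epithelial and 3 fiber arrays, 1 point per array. All 3 fiber arrays lie above all 3 epithelial arrays for GAPDH, from 5.66 to 6.79, while for ACTB epithelial array 3 at 15.7 lies among the fiber arrays.

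Among the genes with large changes, fiber cells had more messenger RNA for the γ-crystallins, the membrane protein MIP, the heat shock protein HSPA6 and the glutathione synthesis enzyme GSS, and epithelial cells had more for the chloride channel regulator CLCA2, the receptor FZD7, the kinase SGK1 and the secreted enzyme GPX3. Of 7157 genes tested, 909 were higher and 858 lower in fiber cells. Of these, 697 and 757 differed at least 2-fold. The 3 arrays of one cell type did not overlap those of the other for 907 of the higher and 843 of the lower genes, and for 40.8% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05, 1321 genes were higher and 1270 lower. Without fiber array 2 the counts fell to 462 higher and 536 lower, and without fiber array 3 to 509 higher. With the GAPDH ratio as a covariate they were 315 and 336, and with the arrays scaled on the hybridization controls 0 and 0 in limma, with 29 and 348 at an unadjusted p under 0.05. Together these 29 and 348 are close to the number of genes that chance gives at that threshold, but they are split unevenly between the directions. Of the called genes, 1765 were tested with that scaling and 0 of them changed sign.

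The largest fitted increase was that of HSPA6, an inducible heat shock protein, at 112 ± 56.4 in epithelial and 1913 ± 223 in fiber cells (SD, n = 3), a log2 fold change of 3.82 (SE 0.30, adjusted p = 0.000178). It was above background on 1 of 3 epithelial arrays, as were CRYGC, MFAP4 and MBP below, so the size of these increases and the rank of HSPA6 are uncertain. ACTA1, skeletal muscle actin, followed with 3.69 (SE 0.35, adjusted p = 0.000183). GSS, which makes glutathione in its final step, rose from 813 ± 535 to 9050 ± 1963, a log2 fold change of 3.62 (SE 0.43, adjusted p = 0.00047). LENEP, a lens protein, rose by 3.47, HOPX, a homeodomain protein, by 3.46, and CPB1, a carboxypeptidase best known from the pancreas, by 3.35. ATP8A2, a lipid flippase, was at least 5.75-fold higher and LSAMP, a neuronal adhesion protein, at least 6.44-fold higher (adjusted p = 0.000178 and 0.0014), both below background on the epithelial arrays. The remaining genes among the 10 largest increases were MIP and CRYGB. Among the called genes named here and in the lists, SCNN1A, MAF, SPTBN1, TFAP2A, KLF6, JAG1, ANK2, MT1G and COL6A1 had at least 1 further probe set whose fold change went the other way. Only 2 of 5 further probe sets of SPTBN1, 1 of 3 of JAG1 and 0 of 1 of MT1G went the same way as the one used.

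Among the genes above background on at least 1 fiber array, the largest fitted decrease was that of CLCA2, a chloride channel regulator of epithelia, from 3535 ± 963 in epithelial to 207 ± 33.6 in fiber cells (SD, n = 3), a log2 fold change of -3.87 (SE 0.28, adjusted p = 0.000178). In that group the Wnt receptor FZD7 followed with -3.54 (SE 0.31), the kinase SGK1 with -3.51 (SE 0.30), the secreted glutathione peroxidase GPX3 with -3.47 (SE 0.31), IGFBP5, which binds insulin-like growth factors, with -3.27 (SE 0.39), and the activin subunit INHBA with -3.27 (SE 0.30). The other 4 of the 10 largest decreases were below background on all 3 fiber arrays and have no place in this order: the sodium channel subunit SCNN1A was at least 3.02-fold lower, the receptor kinase AXL at least 4.55-fold lower, PTPRN2 at least 3.37-fold lower and the myosin light chain MYL9 at least 2.02-fold lower, with adjusted p between 0.000178 and 0.000629.

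Crystallins, the main soluble proteins of the lens, rose in fiber cells. Of 12 tested, 9 were higher, 0 lower and 3 did not pass, with 10 higher when adjusted over the list alone (camera adjusted p = 1.84e-07, and adjusted p = 0.146 with an estimated correlation). The γ-crystallins rose most: CRYGB from 438 ± 103 to 4386 ± 1264 (log2 fold change 3.21, SE 0.29), CRYGC by 3.13 (SE 0.30), CRYGA by 3.07 (SE 0.26) and CRYGD from 5461 ± 2540 to 29778 ± 5929 (2.54, SE 0.35). The β-crystallins CRYBB1, CRYBA4, CRYBA2, CRYBB3 and CRYBA1 rose by 1.86, 1.76, 1.71, 1.53 and 1.39, and under quantile normalization by 1.25, 1.13, 1.06, 1.38 and 0.65. The α-crystallins were abundant in both cell types: CRYAA was at 18236 ± 8336 and 24888 ± 2913, a log2 difference of 0.54 (SE 0.30, adjusted p = 0.235, but 0.88 and 0.0254 without epithelial array 3), and CRYAB at 31773 ± 11910 and 40422 ± 11420, a difference of 0.39 (SE 0.32, adjusted p = 0.425). Under quantile normalization these differences were -0.18 and -0.28. CRYBB2 stood at 28547 ± 7721 and 52678 ± 20737 (log2 fold change 0.85, adjusted p = 0.0747). Its adjusted p was 0.0208 with the array number as a block, 0.0146 with scaling to the median, 0.047 without epithelial array 3 and 0.0454 without fiber array 2, while quantile normalization gave a log2 fold change of 0.25 (adjusted p = 0.46). Controls aside, CRYBB2 was the brightest probe set on epithelial array 2 and on fiber arrays 2 and 3, and CRYAB on epithelial array 3. Whether signal so near the top of the range was compressed, which would shrink these differences, was not tested. CRYGA, CRYGB, CRYGC and CRYGD are close paralogs, and signal shared between their probe sets was not measured. CRYBB3 lost its call without fiber array 2 (adjusted p = 0.0578) or fiber array 3 (adjusted p = 0.0575), and CRYBA1 with the ACTB ratio as a covariate (adjusted p = 0.0603).

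Genes of fiber cell structure rose alongside. Of 14 tested, 10 were higher, 0 lower and 4 did not pass (camera adjusted p = 5.39e-06, and adjusted p = 0.146 with an estimated correlation). MIP, the fiber water channel aquaporin 0, went from 1155 ± 1286 to 8223 ± 4071 (log2 fold change 3.24, SE 0.63, adjusted p = 0.00473), and LIM2, a fiber membrane protein, rose by 2.53 (SE 0.38). BFSP1 and BFSP2, which form the beaded filaments of fiber cells, rose by 2.37 (SE 0.34) and 2.27 (SE 0.29). LGSN, PRX, SPTBN1, BIRC7, TMOD1 and MAF rose by 2.09, 1.98, 1.84, 1.80, 1.30 and 1.18, and MAF lost its call without fiber array 1 (adjusted p = 0.0525). CDH2 (0.38), CAPN3 (-0.19) and PROX1 (-0.24) did not pass, nor did HSF4, which was below background in epithelial cells and at 287 ± 197 in fiber cells (adjusted p = 0.117, or 0.00819 with the array number as a block, 0.0324 without epithelial array 3 and 0.0213 without fiber array 1).

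Genes of the lens epithelium divided. Of 16 tested, 6 were lower, 1 higher and 9 did not pass (camera adjusted p = 0.00356, and adjusted p = 0.255 with an estimated correlation). The gap junction protein GJA1 fell from 4108 ± 1212 to 485 ± 186 (log2 fold change -3.04, SE 0.34, adjusted p = 0.000336), and the water channel AQP1 from 7928 ± 613 to 942 ± 83 (-3.03, SE 0.22, adjusted p = 0.000178). The transcription factors PAX6, FOXE3 and TFAP2A had log2 fold changes of -2.46, -2.42 and -2.13, and the receptor NOTCH2 of -2.25. CLU, a secreted chaperone, was higher, at 7104 ± 712 and 13911 ± 1674 (0.96, SE 0.22, adjusted p = 0.00963), and lost this call under quantile normalization (0.41, adjusted p = 0.178). SOX2, MEIS2, MEIS1, EPHA2, FGFR1, FGFR2, FGFR3, SIX3 and PITX3 did not pass, with log2 differences between -0.51 and 0.56. With the ACTB ratio as a covariate, FGFR3 passed at -1.34 (adjusted p = 0.0265). SIX3 had a value of 1.33 without epithelial array 3 (adjusted p = 0.0142) and of -2.18 with the GAPDH ratio as a covariate (adjusted p = 0.0299).

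**Figure D2:**
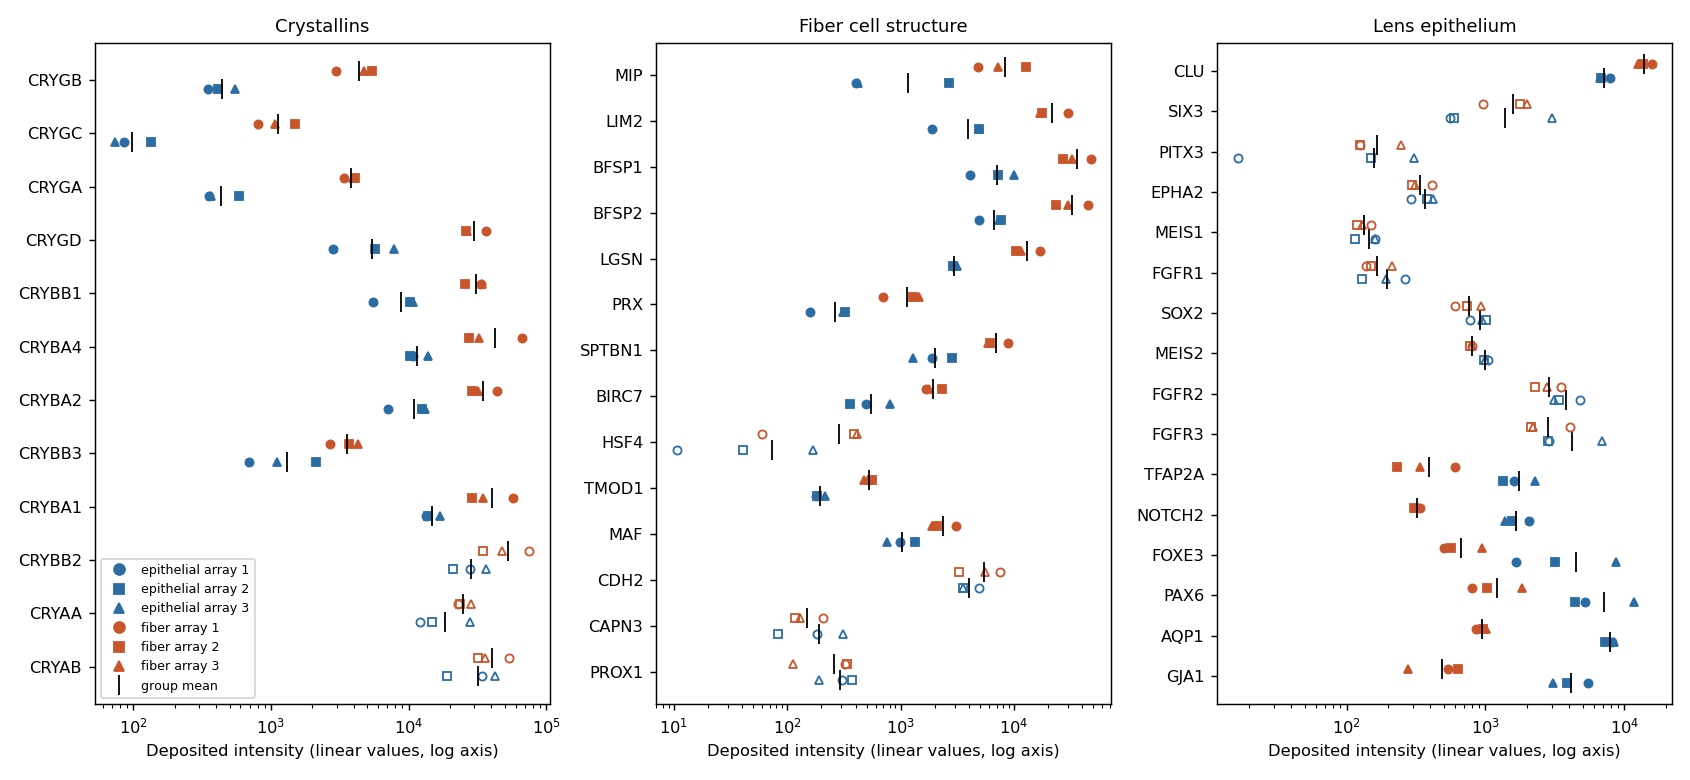
Deposited intensity (linear values on a log axis) is shown per array for every tested crystallin, fiber cell structure gene and lens epithelium gene, with blue points for epithelial and orange points for fiber arrays, black bars for group means and open points for genes that did not pass the test. Fiber arrays lie to the right for the γ-crystallins, where CRYGB averaged 4386 against 438, and to the left for GJA1, AQP1, PAX6 and FOXE3.

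Genes of the capsule and basement membrane, the sheet that surrounds the lens, fell together in fiber cells. Of 16 tested, 12 were lower and 0 higher, with 13 lower when adjusted over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 0.146 with an estimated correlation). NID1, which links laminin to collagen, was at least 4.33-fold lower and the laminin chain LAMB1 at least 4.40-fold lower, both below background on all 3 fiber arrays (adjusted p = 0.000385 and 0.000342). Genes of interferon response and antigen presentation also fell, with 8 of 16 lower and 0 higher (camera adjusted p = 2.39e-05, and adjusted p = 0.146 with an estimated correlation). The class I chains HLA-B and HLA-C went from 1568 ± 546 to 189 ± 109 and from 2953 ± 550 to 468 ± 79.5, log2 fold changes of -2.95 (SE 0.42) and -2.57 (SE 0.25). Probe sets of class I genes are similar in sequence and may share signal.

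Glycolytic genes were lower in fiber cells. Of 19 tested, 9 were lower and 0 higher, with 10 lower when adjusted over the list alone (camera adjusted p = 5.58e-05, and adjusted p = 0.162 with an estimated correlation). The glucose transporter SLC2A3, included in this list, fell from 3396 ± 715 to 387 ± 175 (log2 fold change -3.09, SE 0.32, adjusted p = 0.000235), and the phosphofructokinase PFKP from 1194 ± 222 to 262 ± 67.8 (-2.07, SE 0.27, adjusted p = 0.000728). Of 11 transporters of glucose, amino acids and ascorbate, 6 were lower and 1 higher, with 8 lower when adjusted over the list alone (camera adjusted p = 0.00141, and adjusted p = 0.146 with an estimated correlation). The ascorbate transporter SLC23A2 was at least 4.86-fold lower and the inositol transporter SLC5A3 fell by 2.44 on the log2 scale, while the glutamate transporter SLC1A3 was at least 2.13-fold higher. With the GAPDH ratio as a covariate, the transporter list was not past the test (adjusted p = 0.121).

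Immediate early genes, transcription factors and regulators that cells switch on within minutes of a stimulus, were mostly lower. Of 15 tested, 8 were lower, 2 higher and 5 did not pass (camera adjusted p = 0.0148, and adjusted p = 0.275 with an estimated correlation). FOS was at least 2.82-fold and KLF4 at least 2.26-fold lower (adjusted p = 0.00764 and 0.0027). KLF6 was at least 2.87-fold higher, and JUND rose from 4567 ± 1118 to 9985 ± 877 (log2 fold change 1.15, SE 0.25, adjusted p = 0.00767). With the ACTB ratio as a covariate, FOS and JUND lost their calls (adjusted p = 0.0875 and 0.0652). The list was not past the test without epithelial array 2 (adjusted p = 0.0738), nor with the ACTB or the GAPDH ratio as a covariate (adjusted p = 0.186 and 0.84).

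Genes of protein synthesis were higher in fiber cells. Of 52 cytosolic ribosomal protein genes, 23 were higher and 0 lower, with 33 higher when adjusted over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 0.146 with an estimated correlation). RPS29 went from 8886 ± 2150 to 21214 ± 3646 (log2 fold change 1.27, SE 0.26) and RPS15A rose by 1.22 (SE 0.25). Of 30 translation factors, 12 were higher and 0 lower, with 14 higher when adjusted over the list alone (camera adjusted p = 0.000197, and adjusted p = 0.162 with an estimated correlation), led by EIF5 with 1.96 (SE 0.24) and the poly(A)-binding protein PABPC1 with 1.62 (SE 0.27). Under quantile normalization the ribosomal list was not past the test (median log2 fold change 0.13 in place of 0.75, adjusted p = 0.763), and neither RPS29 nor RPS15A kept its call. The ribosomal median lay at percentile 59 and the translation factor median at percentile 92.9 of random lists matched on mean intensity.

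Mitochondrial respiration genes were also higher on balance. Of 58 oxidative phosphorylation genes, 13 were higher, 2 lower and 43 did not pass (camera adjusted p = 0.000463, and adjusted p = 0.343 with an estimated correlation). NDUFAB1 and NDUFB4 of complex I rose by 1.77 (SE 0.25) and 1.62 (SE 0.23), and NDUFA5 and NDUFB2 of the same complex had log2 fold changes of -1.16 (SE 0.32) and -0.88 (SE 0.24). The list was not past the test under quantile normalization (adjusted p = 0.0574), and its median of 0.49 lay at percentile 75.7 of lists matched on intensity. With scaling on the hybridization controls the list's median was -0.07, where that of all genes was -0.46. NDUFA5 lost its call without epithelial array 1, epithelial array 2, fiber array 1 or fiber array 3 (adjusted p from 0.0672 to 0.0989), and NDUFB2 without epithelial array 2, fiber array 2 or fiber array 3 (0.0746 to 0.117). Both also lost it with scaling to the median (0.0809 and 0.0896) and with the ACTB ratio as a covariate (0.237 and 0.11).

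The lists for heat shock proteins with chaperonin, for the proteasome and for autophagy were higher in fiber cells. Of 27 heat shock protein and chaperonin genes, 12 were higher and 0 lower, with 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.91e-05, and adjusted p = 0.162 with an estimated correlation). The small heat shock protein HSPB1 went from 1916 ± 1131 to 10951 ± 4275 (log2 fold change 2.59, SE 0.46, adjusted p = 0.00311) and the co-chaperone DNAJA1 rose by 2.23 (SE 0.33). Of 32 proteasome genes, 12 were higher and 2 lower, with 16 higher when adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.298 with an estimated correlation). The subunits PSMD6 and PSMA7 rose by 1.78 (SE 0.24) and 1.65 (SE 0.41), while PSMD10 and the activator PSME1 had log2 fold changes of -1.16 and -0.93. PSMA7 lost its call without fiber array 2 (adjusted p = 0.0523), PSMD10 without any array but epithelial array 3 (0.0698 to 0.144) and PSME1 without epithelial array 2, epithelial array 3, fiber array 1 or fiber array 2 (0.0525 to 0.113). PSMD10 and PSME1 also lost it with scaling to the median (0.112 and 0.108) and with the ACTB ratio as a covariate (0.397 and 0.084), and PSMD10 under quantile normalization (0.0734). Autophagy genes had 7 of 25 higher and 0 lower, among them the cargo receptor SQSTM1 with 1.39 (SE 0.25). Their list passed narrowly (camera adjusted p = 0.0438, and adjusted p = 0.207 with an estimated correlation) and did not pass under quantile normalization, scaling to the median or on the hybridization controls, the 60th percentile filter, the common prior variance, the mean of all probe sets, or without epithelial array 2, epithelial array 3 or fiber array 2. Its adjusted p there ranged from 0.051 to 0.115. Scaled on the hybridization controls, the list had a median of -0.18 in place of 0.36, where that of all genes was -0.46.

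Metallothioneins, small proteins that bind zinc and copper, rose in fiber cells, with 6 of 8 higher and 0 lower (camera adjusted p = 0.000848, and adjusted p = 0.275 with an estimated correlation). MT1G went from 4484 ± 853 to 17304 ± 2946 (log2 fold change 1.95, SE 0.24, adjusted p = 0.00057) and MT1F rose by 1.74 (SE 0.27). Metallothionein genes are close paralogs whose probe sets may share signal, and another probe set listed for MT1G went the other way. Antioxidant enzymes went in both directions, with 7 of 34 higher and 8 lower (camera adjusted p = 0.503). Heme oxygenase HMOX1 rose by 2.76 (SE 0.40), and the quinone reductase NQO1 fell by 1.98 on the log2 scale (SE 0.23).

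**Figure D3:**
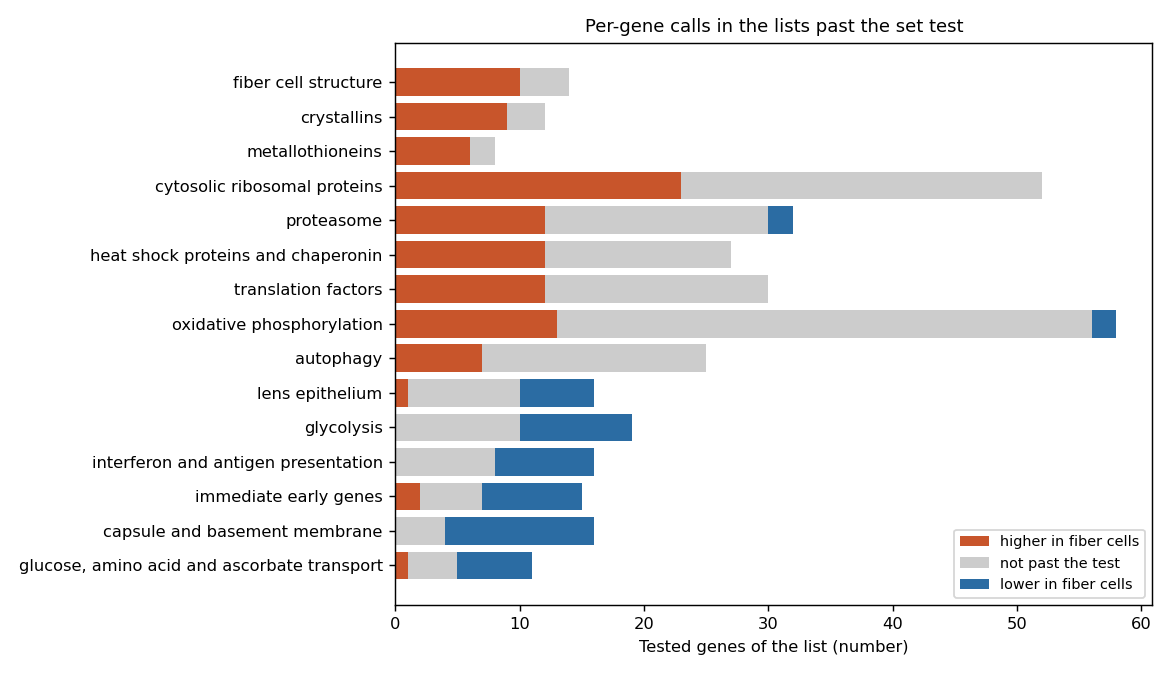
Stacked bars give the number of tested genes that were higher in fiber cells (orange), did not pass the test (gray) or were lower (blue) in the 15 lists past camera with a preset correlation, ordered by median log2 fold change. Ribosomal proteins had 23 of 52 genes higher, and capsule and basement membrane genes 12 of 16 lower.

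**Figure D4:**
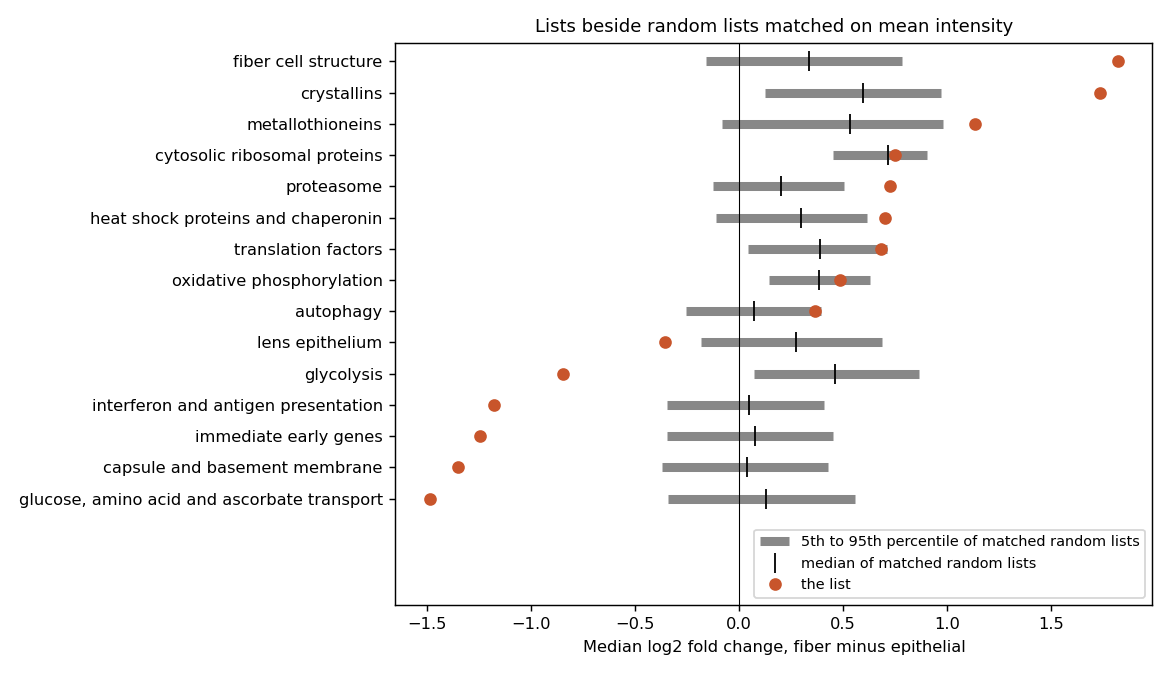
The median log2 fold change (fiber minus epithelial) of each of the 15 lists is an orange point, beside the 5th to 95th percentile (gray) and the median (black) of 10000 random lists of other genes matched on mean intensity. The points for ribosomal proteins, translation factors, oxidative phosphorylation and autophagy lie inside the gray range, at percentiles 59, 92.9, 75.7 and 93.4.

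In the transforming growth factor beta and bone morphogenetic protein list, 5 of 23 genes were higher and 7 lower, with 9 lower when adjusted over the list alone (camera adjusted p = 0.112), with ID3 at least 2.07-fold lower and the decoy receptor BAMBI at -2.04 (SE 0.27), against the receptor ACVR2A with 1.48 (SE 0.27). This list was past the test without fiber array 3 (adjusted p = 0.029), without a filter (0.0276) and with scaling on the hybridization controls (0.0071). Of 18 Wnt pathway genes, 1 was higher and 5 lower (camera adjusted p = 0.129, and 0.027 without a filter). The ligand WNT7A rose by 2.45 (SE 0.33), and the secreted inhibitor SFRP1 fell by 2.71 on the log2 scale (SE 0.30). Of 12 Notch pathway genes, 2 were higher and 2 lower (camera adjusted p = 0.33), with the ligand JAG1 at 1.54 (SE 0.41) and the target HES1 at -1.74 (SE 0.27). JAG1 lost its call without epithelial array 1, fiber array 1 or fiber array 2 (adjusted p = 0.0541, 0.0631 and 0.0649).

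Of 15 cell cycle genes, 3 were lower and 0 higher, with 2 lower when adjusted over the list alone (camera adjusted p = 0.703), with the replication helicase subunit MCM6 at least 1.69-fold lower and below background on the fiber arrays. The cell cycle inhibitor CDKN1B rose by 1.35 (SE 0.28, adjusted p = 0.00655), the 1 called gene of 9 inhibitors and RB family genes (camera adjusted p = 0.507). Of 13 ion and water transport genes, 2 were higher and 5 lower, with 6 lower when adjusted over the list alone (camera adjusted p = 0.112, and 0.0473 without fiber array 1). Carbonic anhydrase CA2 rose by 2.58 (SE 0.35) and the water channel AQP5 by 1.65 (SE 0.49), and the calcium pump ATP2B4 fell by 1.76 on the log2 scale, a size left uncertain because it was above background on 1 of 3 fiber arrays. AQP5 lost its call without any array but epithelial array 3 (adjusted p from 0.051 to 0.106) or with the ACTB ratio as a covariate (0.281), and had a value of -0.11 with the GAPDH ratio as a covariate (adjusted p = 0.941).

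Cytoskeletal lists were mixed. Of 29 actin cytoskeleton genes, 4 were higher and 7 lower, with 9 lower when adjusted over the list alone (camera adjusted p = 0.139, and 0.0251 under quantile normalization). Profilin PFN2 rose by 1.31 (SE 0.24) and tropomyosin TPM1 fell by 2.46 on the log2 scale (SE 0.29). ACTB rose by 1.57 (SE 0.29) in the gene comparison, but its 5' control probe set, which was not tested, overlapped between the cell types, at 1676, 3782 and 541 on epithelial arrays 1 to 3 and at 769, 1652 and 1078 on fiber arrays 1 to 3. Of 16 intermediate filament and spectrin genes, 3 were higher and 2 lower (camera adjusted p = 0.828), with ankyrin ANK2 at 2.31 (SE 0.31) and the keratin KRT19 at least 4.48-fold lower. Of 40 spliceosome genes, 3 were higher and 8 lower, with 9 lower when adjusted over the list alone (camera adjusted p = 0.0739, and 0.0494, 0.0395, 0.0363 and 0.0276 without epithelial array 1, without fiber array 2, under quantile normalization and without a filter). Of 25 histone and chromatin genes, 1 was higher and 7 lower, with 8 lower when adjusted over the list alone (camera adjusted p = 0.132, and 0.0467 with the mean of all probe sets). The splicing factors SRSF5 and PRPF8 had log2 fold changes of -1.67 and -1.48 and the chromatin protein HMGN1 of -1.99. In the other direction, SNRPA1 and SF3B3 of the spliceosome list rose by 1.51 and 1.04 and the histone H2BC21 by 1.14. These increases lost their calls, among other settings, without fiber array 2 (adjusted p = 0.137, 0.0767 and 0.0675).

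Lysosomal genes had 6 of 29 lower and 0 higher (camera adjusted p = 0.0793, and 0.0258, 0.0357, 0.0298, 0.0462 and 0.0467 without epithelial array 3, without fiber array 2, under quantile normalization, without a filter and with the mean of all probe sets), with the cholesterol exporter NPC1 at -1.72 (SE 0.26). Genes of folding in the endoplasmic reticulum had 2 of 19 higher and 3 lower, with 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.528). The stress transcription factor ATF4 rose by 1.59 (SE 0.29), and the chaperone HSPA5 and the disulfide isomerase PDIA3 had log2 fold changes of -1.24 and -1.93. Of 14 citric acid cycle genes, 3 were higher and 1 lower (camera adjusted p = 0.752), with MDH2 at 1.32 (SE 0.29) and SUCLG2 at least 1.54-fold lower, calls that both lost with the ACTB ratio as a covariate (adjusted p = 0.0588 and 0.0528). Of 16 cholesterol synthesis genes, 2 were higher and 1 lower, and 0 when adjusted over the list alone (camera adjusted p = 0.238). These 3 genes, PMVK, SQLE and HMGCS1, lost their calls without 1 of at least 3 different arrays each (adjusted p from 0.0558 to 0.137).

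Among the lists of markers of other cell types, ciliary body genes were past the test with the 60th percentile filter (median -1.54, adjusted p = 0.0186) and not with the 40th, where no such list was. The genes in this paragraph given with array values or only as above or below background were chosen after their values were seen. Hemoglobin HBB was at 2138 on epithelial array 2 and between 204 and 397 on the other 5 arrays. Leukocyte genes had 1 of 6 lower, CD14 at least 1.29-fold, with 1 also higher when adjusted over the list alone, and PTPRC, LYZ and HLA-DRA were below background on all 6 arrays, while HLA-DPB1 was above it on all 3 epithelial arrays. Of 8 photoreceptor and neuronal genes 1 was higher, NEFM at least 1.63-fold, and SAG was above background on 1 array. Pigmented epithelium genes had 0 of 5 called. Ciliary body genes had 1 of 8 higher, MFAP4 with 2.05 (SE 0.43), and 3 lower, among them MFAP5 with -2.56 (SE 0.31). PTGDS lay between 7014 and 22558 on all 6 arrays. Fibroblast genes had 1 of 9 higher, lumican LUM at least 4.21-fold (47.7 ± 3.8 against 647 ± 101), and 3 lower, among them COL6A1 at least 4.26-fold, with COL1A2 and COL3A1 below background on all arrays, COL1A1 above it on epithelial array 2 (229) and fiber arrays 1 and 3 (362 and 229), and PDGFRA and THY1 above it on all 6. The lists for red blood cells, retinal glia, vascular endothelium, smooth muscle and corneal epithelium had 1, 4, 1, 2 and 4 tested genes, too few for the set test. Among these, MBP and CA14 rose by 1.86 and 1.70, MYLK rose by 2.71, with 1 further smooth muscle gene lower when adjusted over the list alone, and the single red blood cell and endothelial genes did not pass. Of the 4 corneal genes, the keratin KRT4 was lower (-1.94, adjusted p = 0.0299, and above background on 1 of 3 fiber arrays, so that its size is uncertain), a call it lost, among other settings, under quantile normalization (0.0531) and without epithelial array 3, fiber array 1 or fiber array 3 (0.0826, 0.0922 and 0.0767).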

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

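Signal was seen in probe sets that the gene comparison does not use, because the annotation lists several genes for each. Of 651 such probe sets at or above the intensity filter, 59 were higher and 73 lower in fiber cells, and those with the largest changes are given here. Probe set 214290_s_at went from 358 ± 265 to 2567 ± 1257 (SD, n = 3), a log2 fold change of 2.81 (limma adjusted p = 0.00409), and 218280_x_at from 202 ± 47 to 1603 ± 352, a log2 fold change of 2.80. Probe set 222088_s_at went from 1701 ± 916 to 135 ± 75.7, below background on all 3 fiber arrays, with a fitted log2 fold change of -3.32 that is no bound, and 208451_s_at from 6337 ± 907 to 644 ± 248, a log2 fold change of -3.28.

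Quantile normalization was planned before the data were examined. The other tests weighed here were chosen after the result was seen, except the comparison of the ribosomal list with lists matched on intensity. That test was written before its own result was seen, though after quantile normalization was found to end the list's call. Difference in cell type, the contrast of the design, stays open and untested as the explanation of each pattern.

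The first pattern is the 1767 genes that differed between the cell types. The real split of the 6 arrays, 1 of 10, gave 1767 genes and the highest of the others gave 0, whether they parted all 3 same-number pairs (4 splits with the real one) or 1 pair (6 splits). With 10 splits the share can never be under 0.05. Each other split puts arrays of both cell types in both groups, so a difference between the types adds to the spread there. That leaves few calls whatever the cause of the difference, so the splits cannot decide on chance. With the ACTB 3' to 5' ratio as a covariate, the called genes' log2 fold changes were a median of 1.02 times those without it (quartiles 0.871 and 1.19), and with the GAPDH ratio 0.984 times (quartiles 0.666 and 1.33). These fits exclude nothing, because the difference of epithelial array 3 from the other epithelial arrays makes up 80.7% of the spread of the ACTB ratio within the cell types and 98.3% of that of the GAPDH ratio. RNA quality cannot be told apart from cell type for the called genes. Of their calls, 1109 were kept with the ACTB and 464 with the GAPDH ratio, and 34 changed sign with the latter.

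The second pattern is the higher signal of ribosomal protein genes in fiber cells. Their median log2 fold change of 0.75 (quartiles 0.40 and 0.93) stayed at 0.65 with the ACTB ratio as a covariate and 0.68 with the GAPDH ratio, and the list stayed past camera with both (adjusted p = 5.4e-07 and 1.41e-05). Since epithelial array 3 sets most of both ratios' spread within the cell types, RNA quality cannot be told apart from cell type here either. A shift of bright probe sets as a class is a candidate explanation: the median lay at percentile 59 of 10000 random lists of equally bright genes, whose 5th and 95th percentiles were 0.45 and 0.90. Quantile normalization brought the median to 0.13. It makes the bright ends of all arrays equal and would also shrink a true rise of such bright genes, so that value cannot decide between them. The comparison with matched lists put crystallins at percentile 100 and glycolysis at 0, so it could have come out otherwise. The 100 brightest probe sets held 15.2% to 19.7% of the summed intensity on the epithelial and 21.2% to 28.3% on the fiber arrays, and whether that shift is itself technical was not tested.

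The third pattern is the lower signal of immediate early genes in fiber cells. Their median of -1.25 lay at percentile 0.01 of lists matched on intensity, against a 5th percentile of -0.35, which argues against a shift tied to brightness. The median was -1.21 with the 5 members that have only a bound set to it and the 3 members without a usable fold left out. RNA quality cannot be told apart from cell type for this list, for the same reason. With the ACTB ratio as a covariate the median was -0.83 (quartiles -1.47 and -0.09) and with the GAPDH ratio -0.93 (quartiles -1.17 and 0.53), against quartiles of -1.62 and -0.02 without, and camera's adjusted p rose from 0.0148 to 0.186 and 0.84. The call ended as the medians shrank by less than a factor of 2 and, with the GAPDH ratio, as the members' median standard error rose from 0.41 to 0.57. Epithelial array 3 had the highest 3' to 5' ratios of its cell type. Its median difference from epithelial arrays 1 and 2 was -0.839 for the immediate early list, where that of the fiber arrays was -1.355. For the ribosomal list these values were -0.034 and 0.783. They rest on 1 array and cannot decide the question.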

How the results depend on the processing

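Alternatives added after the data were examined were the ACTB ratio, the GAPDH ratio as a covariate and the omission of epithelial array 3 with fiber array 1. The cause of the changes listed here was not tested unless stated. Scaling on the hybridization controls gave 0 genes higher and 0 lower, and its construction shows the cause: the controls span a 9.02-fold range over the 6 arrays, which enters every gene's spread. At an unadjusted p under 0.05 limma then had 29 genes higher and 348 lower, together close to the number that chance gives at that threshold but split unevenly. Of the 1765 genes of the main calls tested with that scaling, 0 changed sign. The median of all genes was -0.46 in place of 0.03. Without a filter, 10 lists were lower. Over the fits that left out 1 array, genes higher ranged from 462 to 1057, genes lower from 536 to 910, lists higher from 8 to 9 and lists lower from 5 to 8. The lowest gene counts came without fiber array 2, with 2 arrays in 1 group. The GAPDH ratio as a covariate gave 315 genes higher and 336 lower, turned SIX3 to -2.18 and AQP5 to -0.11, and changed the sign of no other named gene called in either fit. All 13286 probe sets gave 1313 lower. An estimated correlation left 0 lists higher and 0 lower in camera, with 5 and 4 at an unadjusted p under 0.05 and 24 lists past fry. Scaling to the median moved the median of all genes to 0.14 and the share of lower calls from 48.6% to 41.9%. With the array number as a block, 1259 genes were higher and 1166 lower, all 1767 earlier calls among them, and CRYBB2 and HSF4 passed, while no other named gene or list changed its call. Of 148 named genes 132 were called, and 105 kept the call in every fit without 1 array. With the ACTB ratio as a covariate 111 of the 132 kept it and FGFR3 gained 1, and with the GAPDH ratio 61 kept it and SIX3 gained 1. Signal over background limits the dim genes: 82 higher and 333 lower genes have only a bounded fold, 2 called genes were below background on all arrays, and 192 of 777 called genes with further probe sets had at least 1 of opposite sign.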

Other observations

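The gene lists in this part were chosen after the data were examined, so their tests are no independent evidence. They were not compared with random lists matched on mean intensity. Tubulins, the building blocks of microtubules, were higher in fiber cells, with 6 of 12 higher and 0 lower (camera adjusted p = 0.00131 over 5 such lists, 1 of them with only 4 tested genes, and adjusted p = 0.18 with an estimated correlation). TUBA4A went from 275 ± 32.4 to 1748 ± 412 (SD, n = 3), a log2 fold change of 2.51 (SE 0.26, adjusted p = 0.000235), TUBA1A rose by 1.54 (SE 0.24) and TUBA1B by 1.24 (SE 0.20), while TUBB (0.34), TUBB4B (0.27), TUBB3 (0.18) and TUBB6 (-0.12) did not pass. Tubulin genes are close paralogs whose probe sets may share signal. Of 18 ubiquitin-conjugating enzymes, 3 were higher and 0 lower (camera adjusted p = 0.0991), namely CDC34, UBE2B and UBE2Q1 with 1.73, 1.32 and 0.92. Of 9 S100 calcium-binding proteins, 1 was higher and 4 lower (camera adjusted p = 0.079). S100A13 went from 3853 ± 306 to 842 ± 80 (-2.15, SE 0.22, adjusted p = 0.000241), and S100A10 rose by 1.09 (SE 0.33, adjusted p = 0.0322).

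Complement genes were lower in fiber cells, with 6 of 9 lower and 1 higher (camera adjusted p = 0.00714, and adjusted p = 0.305 with an estimated correlation). The protease C1S was at least 3.6-fold and factor B, CFB, at least 2.59-fold lower, and the inhibitor SERPING1 fell from 1008 ± 177 to 279 ± 128 (-1.81, SE 0.32), whereas the surface regulator CD55 rose by 1.48 (SE 0.35, adjusted p = 0.0112). The insulin-like growth factor binding proteins had 3 of 4 tested members lower and 1 higher, fewer members than the 5 required of the lists fixed before. IGFBP3 fell by 2.88 on the log2 scale (SE 0.32), IGFBP6 was at least 2.27-fold lower, and IGFBP7 rose from 4146 ± 1161 to 8598 ± 1541 (1.07, SE 0.26, adjusted p = 0.0147).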
